A study of Rattus norvegicus with 7 samples.

How the data were processed

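Ventricular cardiomyocytes of newborn Wistar rats (postnatal day 0) were transfected with a synthetic miRNA at 25 nM and harvested 72 h later, and mRNA libraries were sequenced on an Illumina instrument, per the labels' protocols and the series' design text. Per the labels' protocols the atria were removed and the cells were left on plastic before use, and the cells that did not attach, mostly cardiomyocytes, were collected. There are 7 libraries of 1 sample each, grouped by the transfected miRNA named in the labels. The labels do not call cel-miR-67 a control; it is treated as one here because the authors' deposited ratios use it as the denominator.

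The authors deposited RPKM values (reads scaled to gene length and library size) for 17141 genes of each library, with Ensembl identifiers, symbols and gene types, and the ratio of each library's RPKM to that of cel-miR-67. STAR 2.7, edgeR and the build Rnor_6.0 are named in the submitters' processing notes, with no role or order. The annotation, the strand setting, the read counter and any filter are not given in the sources used here. The RPKM in the 7 files of single samples equalled those of the series table, and the 117199 deposited ratio values with both terms above 0 equalled the quotient of the RPKM within a relative tolerance of 1e-06. The ratios were not used further, since they are undefined for the 234 genes at 0 in the cel-miR-67 library. RPKM was the unit of analysis throughout.

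Each RPKM value is a whole number of reads divided by the gene's length and the library's size. Lengths and library sizes that give whole reads in all 7 libraries were found for 100% of genes, within a tolerance of 0.002 reads, rising to 0.05 reads for genes with many reads; the median gene length found was 2227 bases. On simulated values of 3243 genes every read number was recovered exactly for 99.5%. The library sizes behind the values were 22674410 reads for cel-miR-67, 27055357 for miR-199a-3p, 24422719 for miR-590-3p, 30663446 for miR-373-3p, 34708142 for miR-302d-3p, 22446204 for miR-33b* and 26792042 for miR-1825. The reads summed over the listed genes were 110% of this size in cel-miR-67, 85.5% in miR-199a-3p, 108% in miR-590-3p, 95.8% in miR-373-3p, 92.1% in miR-302d-3p, 101% in miR-33b* and 100.0% in miR-1825, so the sizes carry a factor per library beyond the sum of the listed reads. The mitochondrial rRNA row took 23.5% to 35.3% of the listed reads. A gene of 2 kb with 3 reads stands at 0.0432 to 0.0668 RPKM. The recovered reads served for exact (Clopper-Pearson) 95% intervals of the ratio of read rates between libraries. These intervals cover counting error only, compare libraries rather than conditions, and carry no pseudocount.

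Changes were computed as log2 of (RPKM + 1) over (cel-miR-67 RPKM + 1), which understates the change of low genes. Genes with a mean of at least 1 RPKM over the 7 libraries entered (12330 genes, 11311 of them protein-coding). With 1 library per group no p-value was computed. Counts used fixed limits of 2-fold per miRNA and 1.5-fold in all 6 miRNA libraries. Shared changes were set against 100 simulations of unchanged libraries, in which the cel-miR-67 library was simulated too and shared by the 6 comparisons. They were drawn with counting error alone, or with normal noise as wide as the spread between the libraries of the 2 miRNAs with a common seed. That spread was taken within 20 groups of genes of like mean expression. The spread of a pair of libraries was the SD across genes of the log2 ratio. Libraries for miR-199a-3p against cel-miR-67 (12330 genes) were also simulated with counting error alone. There the 2-fold limit was passed by 92% of genes changed 2.5-fold, 100% of genes changed 4-fold and 92% of genes changed 0.25-fold. It was passed by 0% of genes changed 1.5-fold and 0.30% of unchanged genes. These rates leave out differences between cultures.

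The 29 gene lists, covering cell cycle, Hippo signalling, heart function, metabolism, stress, reported targets and markers of other cell types, were fixed before the data were examined and written from general knowledge. They held 480 distinct genes, of which 461 were matched by symbol, an older symbol or the Ensembl identifier, and 422 reached a mean of 1 RPKM. For each list and library the median change was ranked among 10000 random lists of the same size, in which each member was replaced by 1 of the 100 protein-coding genes nearest in mean expression. Medians at or below the 2.5 or at or above the 97.5 percentile were called apart, as a description of these libraries. On unchanged lists of 20 genes simulated with counting error alone, 4.58% of 240 pairs of a list and a library were called apart. Members of a list are co-regulated, so real lists can pass these bounds more often than unrelated genes.

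The genes named in the text followed a rule fixed before the data were examined. For each miRNA these were the 8 highest and 8 lowest genes with a mean of at least 5 RPKM and a value above 0 in both libraries, and for the shared changes the 12 genes with the largest smallest change in each direction, under the same limit of 5 RPKM. Unnamed gene models, olfactory and vomeronasal receptors, mitochondrial and MHC genes were left out. From each list 2 to 4 members with the largest change were named, and reported targets, Yap1 and Wwtr1 whatever their value. Some genes that the rule gives are not reported here. A few further members are named after their values were seen, to set a library beside the one described. The order of Fth1 and Best1 on the chromosome is from the assembly GRCr8, whose coordinates are not used because the build differs.

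Alternatives were pseudocounts of 0.1 and 5, a mean of at least 5 RPKM or no filter, scaling to a median log2 ratio of 0, the mean of the other 5 miRNA libraries as reference, protein-coding genes only, scaling to the total reads of the listed genes, and a counting interval that excludes 1. Against the other 5 miRNA libraries the 6 changes of each gene sum to 0, so that reference cannot show a change shared by all 6. A planned analysis of genes with seed sites in the 3 prime UTR was left out because UTR sequences were not used here. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, with a fixed random seed of 1.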

Results

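The study asked which regulatory pathways are shared by microRNAs (miRNAs) that make heart muscle cells divide. Cardiomyocytes from the ventricles of newborn Wistar rats (postnatal day 0) were transfected with a synthetic miRNA at 25 nM, and RNA was taken 72 h after transfection for sequencing of polyadenylated transcripts. There were 7 libraries, 1 for each miRNA: cel-miR-67, a nematode miRNA treated here as the control, and the human sequences miR-199a-3p, miR-590-3p, miR-373-3p, miR-302d-3p, miR-33b* and miR-1825. Values were RPKM (reads scaled to gene length and library size) for 17141 genes. The reads behind them, worked out from the values, came to between 22616067 and 31963293 per library in the listed genes. Mitochondrial genes took 41.0% of these reads in the cel-miR-67 library and between 27.7% (miR-199a-3p) and 41.4% (miR-590-3p) in the others. Changes are given as log2 of (RPKM + 1) over (cel-miR-67 RPKM + 1), among 12330 genes with a mean of at least 1 RPKM over the 7 libraries. With 1 library per miRNA no difference has a replicate check, so values are called higher or lower as descriptions of these libraries.

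One comparison asked which genes differed in the same direction after all 6 miRNAs. Cyclin B1 (Ccnb1), which drives entry into mitosis, was the gene with the largest shared difference, at 10.4 RPKM in the cel-miR-67 library and 44.6 to 107 RPKM in the 6 miRNA libraries, a log2 change of 2.00 to 3.25. Other genes of chromosome segregation and cytokinesis were higher in all 6: the securin gene Pttg1 (log2 1.11 to 2.20), the kinetochore genes Cenpf (1.06 to 2.23) and Knstrn (0.96 to 2.37), and the spindle midzone genes Kif23 (0.91 to 1.62) and Prc1 (0.82 to 2.14). Thymidine kinase Tk1, an enzyme of nucleotide salvage, was at 0.90 to 1.52. The mitochondrial ribosomal gene Mrps12 (1.39 to 2.19), the 14-3-3 gene Ywhah (1.13 to 1.36), the endoplasmic reticulum chaperone gene Canx (0.86 to 1.27), the beta-catenin inhibitor gene Ctnnbip1 (0.85 to 1.51) and the ceramide synthase gene Cers5 (0.83 to 1.22) completed the 12 largest shared increases among named genes with a mean of at least 5 RPKM.

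Lower in all 6 libraries were Tcap, which encodes the titin cap protein of the sarcomere Z-disc, at 60.4 RPKM in the cel-miR-67 library and 17.8 to 25.6 RPKM in the others (log2 -1.71 to -1.20), and sarcolipin (Sln, -1.76 to -0.98), a regulator of the calcium pump. Several genes of the extracellular matrix or its signalling were also lower throughout: periostin (Postn, -1.46 to -0.90), Nov (-2.21 to -0.86), Srpx2 (-1.59 to -0.72), the collagen gene Col15a1 (-1.53 to -0.66) and asporin (Aspn). Aspn stands in the table under 2 gene identifiers between which reads could be split, at -2.27 to -0.70 and -2.29 to -0.65. Cd34 (-1.31 to -0.72), Tmem204 (-1.92 to -0.69), the ephrin receptor gene Epha3 (-1.69 to -0.66) and Herpud1 of endoplasmic reticulum degradation (-1.46 to -0.65) were the rest of the 12 lowest under the same limit.

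In total 72 genes were at least 1.5-fold higher in all 6 libraries and 26 at least 1.5-fold lower. With protein-coding genes only these counts were 57 and 21. The other rows included short RNAs, some of them at 0 RPKM in the control, such as SNORD83 and SNORD65. The simulations cover all gene types. The 6 comparisons share the cel-miR-67 library, so all 7 libraries were simulated as unchanged and compared with the simulated control. With counting error alone a mean of 10.4 genes were higher in all 6 (at most 19 in 100 simulations) and 3.48 lower (at most 10). The simulated control carries only the drawn noise, so these numbers cannot show what an unusual control library would give. With normal noise as wide as the spread between the miR-373-3p and miR-302d-3p libraries the means were 0.56 and 0.51. That noise has 1 width for genes of like mean expression. It therefore leaves out the larger counting error of short genes with few reads, and its lower means are not a stricter comparison. Independent lists of the observed sizes would share 0.000211 and 0.00040 genes. Across genes, the mean correlation between the 6 sets of changes was 0.51, against 0.55 and 0.50 in the simulated sets, and the mean covariance was 0.0817 against 0.0131 and 0.0232. Genes are not independent replicates, and the control, as 1 library, cannot be split to measure its part in the excess. Each other library was also set against the remaining 6: 134 genes were at least 1.5-fold higher and 49 lower in all others than in miR-199a-3p, 98 and 46 than in miR-1825, and between 17 and 33 higher and 6 and 29 lower for the remaining 4. With a pseudocount of 5 instead of 1 the shared counts were 17 higher and 5 lower, with 0.1 they were 129 and 52, and with values scaled to the total reads of the listed genes they were 145 and 6.

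Genes used in G2 and M phase were higher after every miRNA. All 23 measured members of the list, fixed before the data were examined, lay above 0 in all 6 libraries, and 15 of them were among the 72 genes shared by all. The list median was 0.94 after miR-199a-3p, 1.39 after miR-590-3p, 0.90 after miR-373-3p, 0.72 after miR-302d-3p, 0.82 after miR-33b* and 1.66 after miR-1825. In each library this stood at the 100th percentile of 10000 random lists matched on expression. The number of members at least 2-fold higher was 23 after miR-1825, 22 after miR-590-3p, 9 after miR-199a-3p, 8 after miR-373-3p and 4 after each of miR-302d-3p and miR-33b*. After miR-1825 the cytokinesis gene Ect2 was at 2.36, the mitotic kinase gene Aurka at 2.26 and the kinetochore gene Cenpf at 2.23. Beside these, markers of endothelial cells had medians below 0 in all 6 libraries, and smooth muscle markers a median of 0.34 after miR-199a-3p. When the reference was the mean of the other 5 miRNA libraries instead of cel-miR-67, the medians of miR-1825 (0.84) and miR-590-3p (0.28) stayed above 0. Those of miR-199a-3p (-0.15), miR-373-3p (-0.21), miR-302d-3p (-0.39) and miR-33b* (-0.33) were below 0. For each gene the 6 changes against this reference sum to 0 by construction. It therefore ranks the miRNA libraries among themselves and cannot test a rise shared by all 6.

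S phase genes stood higher than random lists in 3 libraries, and the difference from the G2 and M phase list was not tested. Their median over 20 measured members was 0.48 after miR-199a-3p, 0.35 after miR-590-3p and 0.22 after miR-373-3p, each higher than random lists. It was 0.11, 0.07 and -0.0024 after miR-302d-3p, miR-33b* and miR-1825, within the range of random lists. Against the mean of the other 5 miRNA libraries the median of miR-373-3p was 0.0087 and no longer stood apart, while miR-199a-3p and miR-590-3p kept the call. After miR-199a-3p the replication helicase gene Mcm2 was at 0.76 and E2f1 at 0.71, while after miR-1825 Rrm2 of nucleotide synthesis was at 1.14, and the replication licensing genes Cdc6 and Cdt1 were at -0.45 and -0.38. Cell cycle inhibitor genes (14 measured) had a lower median after miR-373-3p (-0.25) and miR-302d-3p (-0.33) and a higher one after miR-1825 (0.39) than random lists. After miR-373-3p and miR-302d-3p Gadd45g was at -1.52 and -1.42 and Cdkn1c, an imprinted cyclin kinase inhibitor, at 1.72 and 2.46. After miR-1825 Cdkn2c was at 1.58 and Cdkn2a at 0.86. The remaining 3 medians, -0.11 after miR-199a-3p, -0.09 after miR-590-3p and 0.11 after miR-33b*, did not stand apart.

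**Figure D1:**
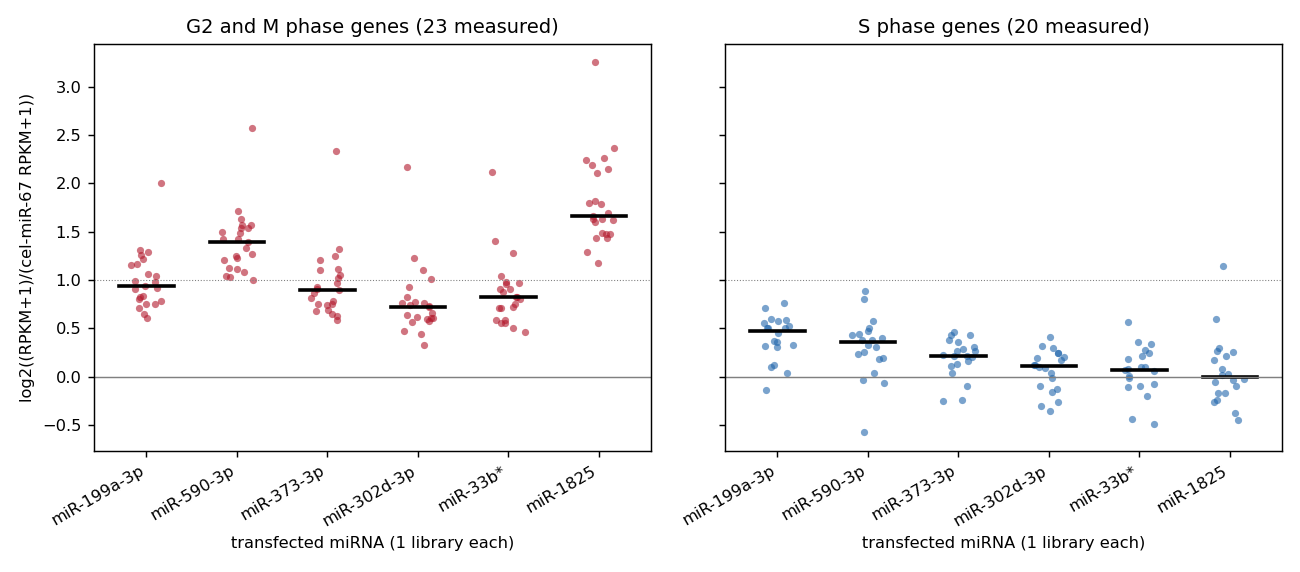
Change of each measured G2 and M phase gene (left, 23 genes) and S phase gene (right, 20 genes) in the 6 miRNA libraries, as log2 of (RPKM + 1) over (cel-miR-67 RPKM + 1); each point is a gene, black bars are medians, and the dotted line marks 2-fold. All points on the left lie above 0, with medians from 0.72 to 1.66, while S phase medians run from -0.0024 to 0.48.

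Genes of the contractile apparatus were lower than random lists in all 6 libraries, by a small amount. Medians over 21 measured sarcomere genes were -0.33, -0.27, -0.15, -0.09, -0.29 and -0.32 for miR-199a-3p, miR-590-3p, miR-373-3p, miR-302d-3p, miR-33b* and miR-1825, and 8 members were below 0 in all 6. With values scaled to the total reads of the listed genes the medians of miR-199a-3p, miR-373-3p and miR-302d-3p turned positive (0.03, 0.04 and 0.16), along with the median of all genes. Against the mean of the other 5 miRNA libraries no sarcomere median stood apart in the lower direction, and those of miR-373-3p and miR-302d-3p were 0.11 and 0.21. Myom2, a protein of the sarcomere M-band, was at -0.35 after miR-199a-3p and at -2.42 to -1.80 after the others. Csrp3, a Z-disc protein gene, was at -1.21 after miR-199a-3p, and the troponin I gene Tnni3 was at -1.34 after miR-1825. The largest changes on the list went the other way. These were the light chain genes Myl4 and Myl7, at 3.32 and 3.06 after miR-373-3p and at 3.38 and 3.29 after miR-302d-3p. Calcium handling and ion channel genes (17 measured) were higher than random lists after miR-199a-3p (median 0.12) and lower after miR-590-3p (-0.24), miR-373-3p (-0.34), miR-302d-3p (-0.25) and miR-1825 (-0.30), with -0.07 after miR-33b*. The ryanodine receptor gene Ryr2 was at -1.07 after miR-373-3p, and phospholamban (Pln) at -0.86 and -0.95 after miR-590-3p and miR-1825. Fetal and stress genes (9 measured) had their lowest median after miR-199a-3p, -0.70, where the natriuretic peptide genes Nppa and Nppb were at -1.73 and -0.85 and the actin-binding repeat gene Xirp2 at -1.48. Their medians were also lower than random lists after miR-590-3p (-0.22), miR-373-3p (-0.23) and miR-33b* (-0.35), and within them after miR-302d-3p (-0.17) and miR-1825 (-0.06). Against the other 5 miRNA libraries those of miR-590-3p and miR-33b* were above 0, and those of miR-199a-3p and miR-373-3p stayed below it. Nppa was at 0.74 after miR-590-3p and 0.71 after miR-1825. Of cardiac transcription factor genes (12 measured) only the median after miR-373-3p, -0.29, stood apart, with Nkx2-5 at -0.76 and Gata6 at -0.60.

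Oxidative phosphorylation genes had their lowest medians after miR-199a-3p and miR-1825, and glycolysis genes were higher than random lists after 4 miRNAs; differences between miRNAs were not tested. The 19 measured genes of oxidative phosphorylation and the citric acid cycle had medians of -0.48 after miR-199a-3p and -0.46 after miR-1825, with -0.22 after miR-33b* and -0.13 after miR-373-3p, all lower than random lists. The last of these was 0.07 when scaled to total reads. Medians of -0.08 after miR-590-3p and -0.09 after miR-302d-3p did not stand apart. The cytochrome oxidase gene Cox6a2 was at -1.21 and Sdha of succinate dehydrogenase at -1.13 after miR-199a-3p, and both were at -1.06 and -0.82 after miR-1825. Fatty acid oxidation genes (19 measured) were lower after miR-1825 (median -0.42, with Cpt1b at -1.53 and Mlycd at -1.15), miR-199a-3p (-0.23), miR-373-3p (-0.19) and miR-302d-3p (-0.19), though 0.09 and 0.05 for miR-199a-3p and miR-302d-3p when scaled to total reads. They were within random lists after miR-590-3p (-0.07) and miR-33b* (0.06), where the carnitine palmitoyltransferase gene Cpt1a was at 1.42. Glycolysis genes (18 measured) were higher after miR-33b* (0.42), miR-590-3p (0.33), miR-373-3p (0.28) and miR-1825 (0.26), and not apart after miR-302d-3p (0.13) and miR-199a-3p (-0.01). The lactate transporter gene Slc16a3 was at 1.01, 1.02, 1.11 and 0.87 in those 4 higher libraries. Phosphofructokinase Pfkp was at -1.66 after miR-199a-3p. Cholesterol synthesis genes (18 measured) were higher after miR-302d-3p (0.38), miR-373-3p (0.31) and miR-590-3p (0.16), with Fdft1 at 0.89 and 0.60 and Fdps at 0.83 and 0.56 after miR-302d-3p and miR-373-3p. Their medians after miR-199a-3p (-0.13), miR-33b* (-0.06) and miR-1825 (0.08) did not stand apart.

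**Figure D2:**
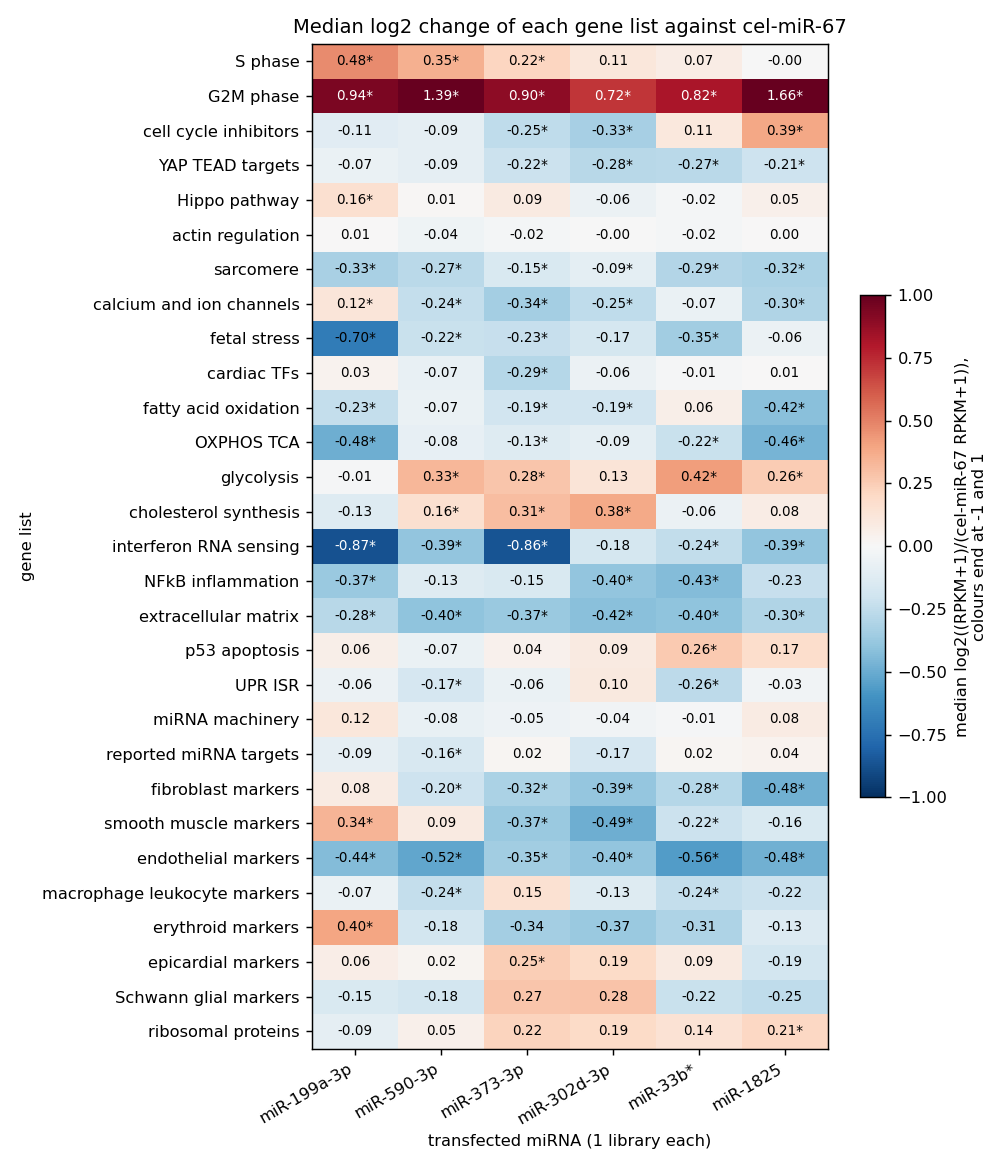
Median log2 change of each of the 29 gene lists (rows) in each miRNA library (columns) against cel-miR-67, printed in the cells; colour gives the value and * marks a median called apart from random lists. G2 and M phase genes stand out as the row with the highest values (0.72 to 1.66), while endothelial markers are below 0 in every column (-0.56 to -0.35).

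Endothelial markers were lower than random lists in all 6 libraries, and fibroblast markers in all but miR-199a-3p. Extracellular matrix genes (19 measured) had medians of -0.28, -0.40, -0.37, -0.42, -0.40 and -0.30 in the order above, lower than random lists in all 6, although 0.08 for miR-199a-3p when scaled to total reads. Against the other 5 miRNA libraries that of miR-302d-3p alone stayed lower than random lists (-0.14), and those of miR-199a-3p and miR-1825 were 0.24 and 0.032. Besides Postn, the crosslinking enzyme gene Lox was at -1.46 after miR-302d-3p and the matrix gene Thbs1 at -1.16 after miR-33b*. Endothelial markers (6 measured, 1.26 to 15.6 RPKM in the control) were lower in all 6, with medians of -0.44, -0.52, -0.35, -0.40, -0.56 and -0.48; Plvap was at -0.94 after miR-199a-3p and Eng at -0.79 after miR-33b*. Against the other 5 miRNA libraries no endothelial median stayed apart, and 3 were above 0 (0.051 after miR-373-3p, 0.11 after miR-302d-3p and 0.029 after miR-33b*). Fibroblast markers (11 measured) were lower after miR-590-3p (-0.20), miR-373-3p (-0.32), miR-302d-3p (-0.39), miR-33b* (-0.28) and miR-1825 (-0.48), and at 0.08 after miR-199a-3p. Against the other 5 miRNA libraries the fibroblast medians of miR-590-3p and miR-33b* were above 0, and those of miR-373-3p, miR-302d-3p and miR-1825 stayed below it. S100a4 was at -1.80 and -2.37 after miR-373-3p and miR-302d-3p, Tcf21 at -1.41 after miR-1825, and gelsolin (Gsn) at 1.27 after miR-199a-3p. Smooth muscle markers (11 measured) were higher after miR-199a-3p (0.34, with Acta2 at 0.79) and lower after miR-373-3p (-0.37), miR-302d-3p (-0.49) and miR-33b* (-0.22), with 0.09 after miR-590-3p and -0.16 after miR-1825. Calponin (Cnn1) went the other way, at 1.37, 1.39 and 1.73 in those 3 libraries, and was higher in all 6 (0.76 to 1.73). Macrophage and leukocyte markers (10 measured) were lower after miR-590-3p and miR-33b* (-0.24 each), and between -0.22 and 0.15 otherwise. Erythroid markers (4 measured) were higher after miR-199a-3p (0.40) and between -0.37 and -0.13 otherwise. Epicardial markers (7 measured) were higher after miR-373-3p (0.25) and between -0.19 and 0.19 otherwise. The 1 measured Schwann cell marker lay between -0.25 and 0.28 and did not stand apart.

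Interferon and RNA sensing genes (16 measured) were lower than random lists in 5 libraries. Their medians were -0.87 after miR-199a-3p, -0.86 after miR-373-3p, -0.39 after miR-590-3p and miR-1825, and -0.24 after miR-33b*, and -0.18 after miR-302d-3p, which did not stand apart. Against the other 5 miRNA libraries those of miR-199a-3p (-0.44) and miR-373-3p (-0.33) stayed lower, while those of miR-590-3p and miR-33b* (0.21 each) and miR-1825 (0.031) were above 0. The antiviral gene Mx2 was at -1.87 and Usp18 at -1.72 after miR-199a-3p, and Irf7 was at -1.80 after miR-373-3p; 10 members were below 0 in all 6 libraries. The chemokine gene Cxcl10 was at 1.47 after miR-1825. NF-kB and inflammation genes (10 measured) were lower after miR-199a-3p (-0.37, with Lcn2 at -1.51 and Ccl2 at -1.45), miR-302d-3p (-0.40, with Ptgs2 at -1.29 but Ccl20 at 1.39) and miR-33b* (-0.43), and between -0.23 and -0.13 otherwise. Unfolded protein and integrated stress response genes (15 measured) were lower after miR-33b* (-0.26, with Herpud1 at -1.46 and Sdf2l1 at -0.81) and miR-590-3p (-0.17), and between -0.06 and 0.10 otherwise. Genes induced by p53 (14 measured) were higher after miR-33b* (0.26, with Cdkn1a at 0.55 and Trp53inp1 at 0.47) and between -0.07 and 0.17 otherwise. Ribosomal protein genes (20 measured) were higher after miR-1825 (0.21) and between -0.09 and 0.22 otherwise. Actin regulators (29 measured) and miRNA machinery genes (10 measured) did not stand apart in any library, with medians of -0.04 to 0.01 and -0.08 to 0.12. Of all 174 pairs of a list and a library, 24 were called higher and 62 lower. Against the mean of the other 5 miRNA libraries 29 of these 86 calls were kept, 30 kept the direction alone and 27 medians changed sign. That reference takes out any change shared by all 6 miRNAs, since the 6 changes of each gene sum to 0.

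Genes of the Hippo pathway and genes reported in earlier work as targets of these miRNAs were examined one by one. The kinase gene Stk38l was lower in all 6 libraries, at -1.30 after miR-199a-3p, -0.55 after miR-590-3p, -1.17 after miR-373-3p, -1.01 after miR-302d-3p, -0.86 after miR-33b* and -0.47 after miR-1825. Cofilin 2 (Cfl2), an actin-severing protein gene, was at 155 RPKM in the control and at -1.06, -1.15, -1.40 and -0.96 after miR-199a-3p, miR-373-3p, miR-302d-3p and miR-1825, but -0.51 after miR-33b* and 0.34 after miR-590-3p. The Hippo kinase gene Lats2 was at -1.28 and -1.27 and the receptor gene Tgfbr2 at -1.46 and -1.74 after miR-373-3p and miR-302d-3p, against -0.40 to 0.23 for both genes after the other 4 miRNAs. Clic5 was at -1.12 and Taok1 at -0.49 after miR-199a-3p, against -0.24 to 0.13 elsewhere. Homer1 was at -0.28 after miR-199a-3p and -0.30 after miR-590-3p, and Hopx at 0.38 and -0.10. The transcriptional coactivator gene Yap1 was slightly higher in all 6 libraries, at 0.25 to 0.45, and Wwtr1 was between -0.41 and 0.52. Over 12 measured reported targets the median stood apart only after miR-590-3p (-0.16), with values from -0.17 to 0.04 in the others. The Hippo pathway list (29 measured) was higher after miR-199a-3p (0.16) and between -0.06 and 0.09 elsewhere. Transcripts known to be induced by YAP (21 measured) include Lats2, which is also on the Hippo pathway and reported target lists. Their median was lower than random lists after miR-373-3p (-0.22), miR-302d-3p (-0.28), miR-33b* (-0.27) and miR-1825 (-0.21). After miR-199a-3p and miR-590-3p it was at -0.07 and -0.09. Against the mean of the other 5 miRNA libraries none of these calls was kept, with -0.0014 after miR-373-3p, -0.070 after miR-302d-3p, -0.10 after miR-33b* and 0.10 after miR-1825. The muscle ankyrin repeat gene Ankrd1, at 2753 RPKM in the control, was at -1.39 to -0.43, and the secreted factor gene Ccn2 at -1.14 to -0.30.

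Each miRNA was then compared with cel-miR-67 by itself. After miR-199a-3p 128 genes were at least 2-fold higher and 188 lower. The ferritin heavy chain gene Fth1, which stores iron, was the lowest of the named genes, at 195 RPKM in the control and 22.3 RPKM after the miRNA, 8.78-fold lower, from 3678 and 500 reads. Best1, its neighbour on the chromosome in the rat assembly GRCr8, was at -2.75, and reads of the pair could be shared. Ferritin also has processed copies among which reads could be split. The tetraspanin gene Cd151 was at -2.57, Ankrd13c at -2.42, the sodium channel subunit gene Scn3b at -2.04, Mx2 at -1.87, Reg3b at -1.85 and the miRNA gene Mir22 at -1.83. Besides Ccnb1, the highest were Bex4 (1.85), the coactivator gene Cited1 (1.58), Aif1l (1.54), Depdc1 of mitosis (5.46 RPKM in the control and 17.2 RPKM after the miRNA) and 3 small nucleolar RNA rows, SNORD113 (1.99 and 1.61) and SNORD18 (1.51), which rest on 6 to 9 reads in the control.

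After miR-590-3p 186 genes were at least 2-fold higher and 94 lower. The highest named genes were Ccnb1 (2.57), the ubiquitin conjugating gene Ube2t (2.05), Mrps12 (1.90), Depdc1 (1.79), Pttg1 (1.73), Aurka (1.71), the centrosome kinase gene Nek2 (1.66) and Knstrn (1.66). The lowest was myoglobin (Mb), which binds oxygen in muscle, at 252 RPKM in the control and 55.6 RPKM after the miRNA (-2.16). Reg3b (-2.08), Adamtsl2 (-1.94), Myom2 (-1.80), elastin (Eln, -1.41), Sln (-1.38) and Adck3 (-1.36) followed, and the 7SK RNA row (-1.57) rests on 20 and 6 reads.

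After miR-1825 247 genes were at least 2-fold higher and 201 lower. Ccnb1 stood at 107 RPKM (3.25), followed by Ube2t (2.49), Knstrn (2.37), Ect2 (2.36), Nek2 (2.32), Aurka (2.26), Cenpf (2.23) and Pttg1 (2.20). Mb was at 39.3 RPKM (-2.65) and Myom2 at -2.42. The gamma tubulin gene Tubg1 (-2.25), Ankrd13c (-2.21), the hyaluronan binding gene Cemip (-2.07), Uqcrq of respiratory complex III (-2.03) and Adamtsl2 (-1.96) were also among the lowest. Genes at least 2-fold higher after both miR-590-3p and miR-1825 numbered 124 and genes lower after both 34. Over all pairs of miRNA libraries the observed mean was 103 genes, both directions together. Simulated unchanged libraries with a shared simulated control and counting error alone gave a mean of 12.7. The spread of the pair (SD of the log2 ratio across genes) of 0.332 was the second smallest of the 21 pairs of libraries.

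After miR-33b* 160 genes were at least 2-fold higher and 153 lower. The growth factor gene midkine (Mdk) was at 5.75 RPKM in the control and 66.5 RPKM after the miRNA (3.32), and Mir675, a miRNA row inside the imprinted H19 transcript, was at 2.58. Lsp1 (2.18), Ccnb1 (2.12), Mrps12 (2.01), Cnn1 (1.73), Pttg1 (1.73) and the fatty acid desaturase gene Scd2 (1.69) were next. The lowest were Adamtsl2 (-2.55), Eln (-2.35), Myom2 (-2.34), Nov (-2.21), the sulfide oxidation gene Ethe1 (-1.92), Tmem204 (-1.78), Sln (-1.76) and Wisp2 (-1.72).

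The miRNAs miR-373-3p and miR-302d-3p share the seed, bases 2 to 8 of the miRNA, which guides pairing with targets. Their libraries were compared to ask whether a shared seed goes with a shared profile. They shared 7 of their 8 highest named genes: the atrial light chain genes Myl4 (3.32 and 3.38) and Myl7 (3.06 and 3.29), Mdk (2.80 and 3.14), Bex4 (2.52 and 3.02), Ccnb1 (2.33 and 2.17), Lsp1 (1.96 and 2.22) and Mir675 (1.99 and 2.38), for miR-373-3p and miR-302d-3p in turn. Myl4 was at 83.2 RPKM in the control and at 838 and 876 RPKM after the miRNAs, from 1500, 20436 and 24168 reads, and Myl7 at 18.9, 165 and 194 RPKM. After the other 4 miRNAs, which do not share this seed, Myl4 was at -0.95 to 1.12 and Myl7 at -0.19 to 0.21. The sites that pair with the seeds of miR-33b* and miR-1825 nevertheless hold a run of bases of the pair's site, GCACT, at shifted positions. Other genes were not particular to the pair: after miR-33b* Mdk was at 3.32, Mir675 at 2.58, Lsp1 at 2.18, Adamtsl2 at -2.55 and Eln at -2.35, after miR-199a-3p Bex4 was at 1.85, and Ccnb1 was high in all 6 libraries. The glucose transporter gene Slc2a1 was at 2.28 after miR-302d-3p, with 1.64 after miR-373-3p, and a SNORD113 row was at 1.89 after miR-373-3p from 6 reads in the control. At the bottom were the small heat shock protein gene Hspb6 (-3.16 and -3.29), Reg3b (-3.15 and -3.69), Adamtsl2 (-3.05 and -3.26), Eln (-2.99 and -3.54), Wfdc1 (-2.82 and -3.41) and Xirp2 (-2.56 and -2.78). Mb (-2.27) and Myom2 (-2.26) were among the 8 lowest after miR-373-3p, and the integrin gene Itga7 (-2.82) and matrix Gla protein (Mgp, -2.60) after miR-302d-3p.

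After miR-373-3p 142 genes were at least 2-fold higher and 230 lower, and after miR-302d-3p 162 and 260. Of these 101 were higher in both, 165 lower in both and 0 opposite. The observed mean over all pairs of miRNA libraries was 103 genes, both directions together. The next largest overlap, 124 higher and 34 lower, was that of miR-590-3p and miR-1825. Simulated unchanged libraries with a shared simulated control and counting error alone shared 12.7 per pair. The spread between both libraries, which does not involve the control, was 0.215, the smallest of the 21 pairs, against 0.332 to 0.480 for the rest. Counting alone would give 0.135, and 52 genes still differed by at least 2-fold between the pair. Interferon genes were among the lists with different medians, at -0.86 and -0.18, a difference that was not tested. With a pseudocount of 5 the spread was 0.132. It cannot be set beside the 0.135 from counting, which was computed with a pseudocount of 1.

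**Figure D3:**
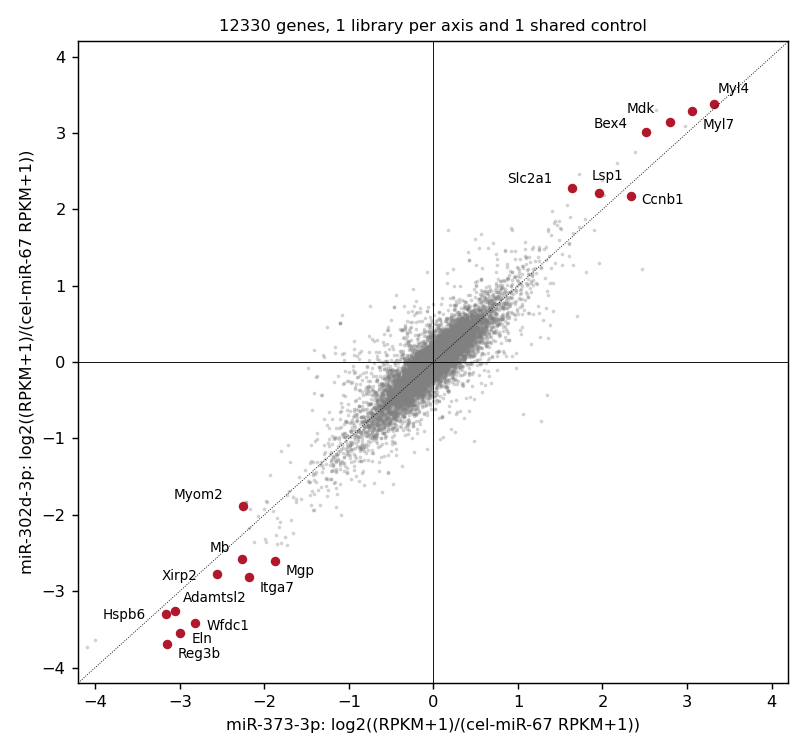
Log2 change of (RPKM + 1) against cel-miR-67 after miR-373-3p (horizontal) and miR-302d-3p (vertical) for 12330 genes, with the named protein-coding genes in red; the dotted line marks equal change. Myl4 and Myl7 lie at the upper right (3.06 to 3.38) and Reg3b, Eln, Hspb6, Adamtsl2 and Wfdc1 at the lower left (-3.69 to -2.82); the shared control adds to the alignment.

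**Figure D4:**
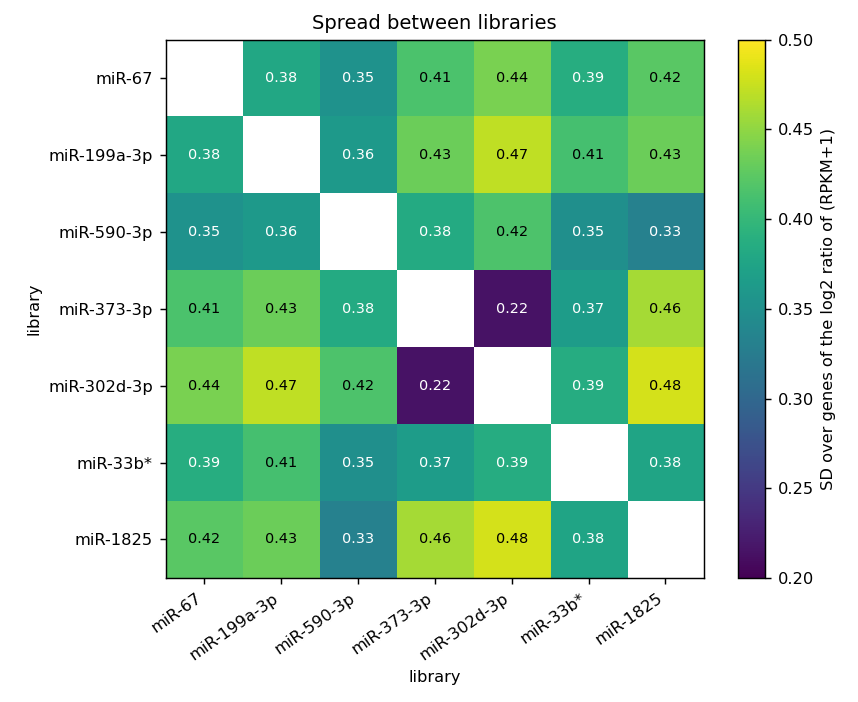
Spread between each pair of the 7 libraries, as the SD over 12330 genes of the log2 ratio of (RPKM + 1); each cell is a pair and colour gives the SD. The miR-373-3p and miR-302d-3p pair has the smallest spread, 0.215, and the miR-302d-3p and miR-1825 pair the largest, 0.480.

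The balance of higher and lower genes depends on how libraries are scaled. As deposited, the median change of all genes was between -0.0034 and 0.0151 in every library. Scaled instead to the total reads of the listed genes, an alternative chosen after seeing the data, this median moved to 0.30 after miR-199a-3p, 0.01 after miR-590-3p, 0.17 after miR-373-3p, 0.23 after miR-302d-3p, 0.10 after miR-33b* and 0.11 after miR-1825. The numbers of higher and lower genes then became 403 and 84 after miR-199a-3p, 222 and 141 after miR-373-3p, 294 and 170 after miR-302d-3p, 225 and 104 after miR-33b*, and 323 and 148 after miR-1825, while those of miR-590-3p stayed near theirs, at 184 and 87. List percentiles compare genes within a library, so the changes above are stated relative to the other genes of that library.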

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

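All explanatory tests in this part were chosen after the results were seen. In 3 lists the median was higher than random lists after 1 miRNA and lower after another, with 1 library on each side, and none of these differences was tested. Cell cycle inhibitor genes stood 0.72 higher after miR-1825 (0.39) than after miR-302d-3p (-0.33) on the log2 scale. Calcium handling and ion channel genes stood 0.46 higher after miR-199a-3p (0.12) than after miR-373-3p (-0.34). Smooth muscle markers stood 0.83 higher after miR-199a-3p (0.34) than after miR-302d-3p (-0.49).

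For the higher G2 and M phase genes in all 6 miRNA libraries, the lowest list median over 3 scalings was 0.71. This minimum cannot decide on scaling, since median scaling changed little and scaling to total reads moved the median of all genes up. Scaling is argued against within each library, since a factor per library moves genes of like expression alike. The list median stood at the 100th percentile of random lists matched on expression in all 6 libraries. The lowest, 0.72 after miR-302d-3p, compares with an upper bound of 0.19 for random lists there. Markers gave no sign of a larger share of fibroblasts and endothelial cells outside miR-199a-3p, where their highest median was -0.20. They cannot exclude it, since markers can change within cells. Against the other 5 miRNA libraries medians of both lists were above 0 in some libraries, such as miR-33b*. Changes of each gene against that reference sum to 0 over the 6 libraries, so this cannot decide either. Epicardial cells stay open outside miR-199a-3p, with markers at 0.25 after miR-373-3p and 0.19 after miR-302d-3p. So do macrophages (0.15 after miR-373-3p) and smooth muscle cells (0.09 after miR-590-3p). After miR-1825, where the G2 and M phase median was highest (1.66), epicardial, macrophage and smooth muscle markers were at -0.19, -0.22 and -0.16. Markers did not rise in every type other than cardiomyocytes after miR-199a-3p: endothelial markers were at -0.44 beside smooth muscle markers at 0.34. This cannot exclude a larger share of every such type, since 2 of the 6 endothelial markers were above 0. Endothelial medians were also below 0 in all 6 libraries, which share the control. Smooth muscle cells, erythroid cells (markers at 0.40) and, with medians of 0.08 and 0.06, fibroblasts and epicardial cells stay open. A cel-miR-67 library out of line by itself and an effect of the miRNAs (lowest median as deposited 0.72) cannot be told apart, because there is 1 control library.

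The miR-373-3p and miR-302d-3p libraries were the closest of all pairs. A single library deposited under both names is argued against, since the spread between the 2 was 1.60 times that from counting alone. A shared culture or preparation day cannot be told apart from the shared seed: the labels give no day for any library, so the gap to the next smallest spread, 0.332, cannot be assigned. The shared seed, the biological explanation, stays open as a hypothesis, and its target sites were not tested.

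Myl4 and Myl7, light chain genes of atrial muscle, were higher in the miR-373-3p and miR-302d-3p libraries, at 3.06 to 3.38. The protocol in the labels removed the atria. Across 8 other measured genes used in atria no rise of like size was seen: the higher of the 2 medians was -0.033 (SD 0.68, after miR-373-3p) and the highest member, after miR-302d-3p, was at 0.96. This cannot exclude cells of the atria, since the list was chosen after results were seen and Nppa already stood at 1860 RPKM in the control. Bmp10, at 0.765 RPKM in the control, was at 1.70 and 2.04 RPKM after miR-373-3p and miR-302d-3p, a change that the pseudocount understates. Bmp10 was also at 1.39 and 1.35 RPKM after miR-590-3p and miR-1825, and at 0.585 and 0.538 RPKM after miR-199a-3p and miR-33b*. Counting error is argued against, with a lowest bound of 3.03 over the 4 counting intervals. An effect of the shared seed on the light chain genes stays open as a hypothesis without a replicate.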

How the results depend on the processing

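The 12 counts of genes past 2-fold, both counts of genes past 1.5-fold in all 6 miRNA libraries, the spread between miR-373-3p and miR-302d-3p and the list calls were recomputed under settings fixed before the data were examined, and under 3 added after seeing the data: protein-coding genes only, scaling to the total reads of the listed genes, and a counting interval that excludes 1. Each limit of size stands on the log2 scale with a pseudocount, so a larger pseudocount or a stricter filter on low values leaves fewer genes past it by construction. Scaling to a median log2 ratio of 0 and the counting interval left each count they were run on within 1.5 times, and so did the absence of a filter for the counts and the spread. With a pseudocount of 0.1, 255, 317, 289, 301, 304 and 389 genes were at least 2-fold higher in miR-199a-3p, miR-590-3p, miR-373-3p, miR-302d-3p, miR-33b* and miR-1825 in turn, and 296, 202, 394, 462, 300 and 403 were lower, in the same order of miRNAs. There, 129 genes were higher in all 6 and 52 genes were lower in all 6. With a pseudocount of 5, 38, 60, 32, 42, 33 and 104 genes were at least 2-fold higher in miR-199a-3p, miR-590-3p, miR-373-3p, miR-302d-3p, miR-33b* and miR-1825 in turn, and 71, 21, 69, 99, 43 and 59 were lower, in the same order of miRNAs. There, 17 genes were higher in all 6, 5 genes were lower in all 6 and the spread was 0.132. With a mean of at least 5 RPKM, genes at least 2-fold higher numbered 76 in miR-199a-3p, 83 in miR-373-3p, 84 in miR-302d-3p, 79 in miR-33b* and 164 in miR-1825, and 107, 37, 146, 169, 92 and 123 genes were lower in miR-199a-3p, miR-590-3p, miR-373-3p, miR-302d-3p, miR-33b* and miR-1825 in turn. There, 16 genes were lower in all 6. Against the mean of the other 5 miRNA libraries, which holds effects of those miRNAs, genes at least 2-fold higher numbered 28 in miR-590-3p, 39 in miR-373-3p, 60 in miR-302d-3p, 56 in miR-33b* and 77 in miR-1825, and genes at least 2-fold lower numbered 43 in miR-590-3p, 88 in miR-373-3p, 98 in miR-302d-3p, 33 in miR-33b* and 125 in miR-1825. With protein-coding genes only, genes at least 2-fold higher numbered 75 in miR-199a-3p and 104 in miR-33b*, and genes at least 2-fold lower numbered 47 in miR-590-3p. With values scaled to the total reads of the listed genes, genes at least 2-fold higher numbered 403 in miR-199a-3p, 222 in miR-373-3p and 294 in miR-302d-3p, and genes at least 2-fold lower numbered 84 in miR-199a-3p, 141 in miR-373-3p and 170 in miR-302d-3p. There, 145 genes were higher in all 6 and 6 genes were lower in all 6. 

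Of the 174 pairs of a list and a library, 86 stood apart from random lists as reported, 85 with a pseudocount of 0.1, 85 with median scaling, 86 with scaling to total reads and 61 against the other 5 miRNA libraries. Among the 86, direction and call were kept in 83 with a pseudocount of 0.1 and 85 with median scaling, and the call alone was lost in 3 and 1. Against the other 5 miRNA libraries 29 kept both, 30 kept the direction without the call and 27 changed sign. For each gene the changes against that reference cancel out over all miRNA libraries. Lists that changed alike in every library therefore lose calls or change sign there by construction, which does not bear on the change against cel-miR-67. The medians that changed sign there were -0.15 in miR-199a-3p, -0.21 in miR-373-3p, -0.39 in miR-302d-3p and -0.33 in miR-33b* for G2 and M phase, 0.10 in miR-1825 for YAP targets, 0.11 in miR-373-3p and 0.21 in miR-302d-3p for sarcomere and 0.023 in miR-302d-3p and 0.044 in miR-1825 for calcium and ion channels. Others were 0.24 in miR-590-3p and 0.12 in miR-33b* for fetal and stress genes, 0.076 in miR-373-3p and 0.011 in miR-302d-3p for fatty acid oxidation, 0.16 in miR-373-3p and 0.013 in miR-33b* for oxidative phosphorylation and -0.048 in miR-1825 for glycolysis. Others were 0.21 in miR-590-3p, 0.21 in miR-33b* and 0.031 in miR-1825 for interferon genes, 0.069 in miR-33b* for NF-kB genes, 0.24 in miR-199a-3p and 0.032 in miR-1825 for extracellular matrix and 0.063 in miR-590-3p and 0.18 in miR-33b* for fibroblast markers. Others were 0.051 in miR-373-3p, 0.11 in miR-302d-3p and 0.029 in miR-33b* for endothelial markers. With scaling to total reads 77 kept both, 2 lost the call alone and 7 medians changed sign, all toward the shift of all genes in that library, while the percentiles among random lists take up that shift too: the medians were 0.029 in miR-199a-3p, 0.042 in miR-373-3p and 0.16 in miR-302d-3p for sarcomere, 0.090 in miR-199a-3p and 0.054 in miR-302d-3p for fatty acid oxidation, 0.067 in miR-373-3p for oxidative phosphorylation and 0.075 in miR-199a-3p for extracellular matrix. Except where the construction of a setting gives it, the cause was not tested. No paired analysis was possible because each group has 1 library and no result comes from a test across libraries. The planned median of genes with a seed site in the 3 prime UTR, with its alternatives, was not run, since no 3 prime UTR annotation or sequence was used here. Depth limits the low genes: 3 reads in a gene of 2 kb correspond to 0.0432 to 0.0668 RPKM across the libraries, and the spread from counting alone was 0.135 for the closest pair.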

Other observations

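Both lists in this part were chosen after some results were seen, and no explanation was tested. A list of 16 imprinted genes that regulate growth was written after Cdkn1c, a member of it, and small RNAs inside H19 and Meg3 had been seen, so its medians are given without a comparison to random lists. Its 11 measured members had medians of 0.53 after miR-33b*, 0.41 after miR-373-3p, 0.35 after miR-302d-3p, 0.28 after miR-1825, 0.20 after miR-199a-3p and 0.03 after miR-590-3p, and at most 4 members were at least 1.5-fold higher in any library. The receptor gene Igf2r, which clears the growth factor IGF2, was at 77.8 RPKM in the control and at 176, 171 and 183 RPKM after miR-373-3p, miR-302d-3p and miR-33b*. The adaptor gene Grb10 was at 57.1 RPKM in the control and 67.7 to 104 RPKM in the 6 libraries, and Cdkn1c at 7.26 and 12.8 RPKM after miR-373-3p and miR-302d-3p (log2 1.72 and 2.46). Mest was at 0.88 after miR-302d-3p and -0.56 after miR-590-3p, and Peg3 at 0.94 after miR-199a-3p. Mir675, which lies inside H19, was at 31.5 RPKM in the control and 128, 168 and 194 RPKM after miR-373-3p, miR-302d-3p and miR-33b*.

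Other genes used in atria did not share one direction with Myl4 and Myl7. Dkk3 was at 25.4 RPKM in the control and at 46.7, 50.4 and 53.9 RPKM after miR-373-3p, miR-302d-3p and miR-33b*, while Adm was at -0.95 to -0.15 and Kcnj3 at -0.92 to -0.12 in all 6 libraries. The list median stood apart only after miR-590-3p, at -0.39, and was -0.14, -0.03, -0.16, -0.21 and -0.22 after miR-199a-3p, miR-373-3p, miR-302d-3p, miR-33b* and miR-1825.

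The share of listed reads from mitochondrial genes was 41.0% in cel-miR-67, 41.4% in miR-590-3p, 37.9% in miR-33b*, 35.5% in miR-1825, 33.2% in miR-373-3p, 30.6% in miR-302d-3p and 27.7% in miR-199a-3p. Genes at least 1.5-fold higher in every other library than in miR-199a-3p numbered 134, more than for any other library taken in turn. For miR-1825 taken in turn, 5 members of the G2 and M phase list were at least 1.5-fold higher there than in each of the other 6 libraries.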
